A study of Coryphaena hippurus with 27 samples.

How the data were processed

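Small RNA libraries of whole mahi-mahi embryos or larvae were sequenced on an Illumina NextSeq by the study. Animals were sampled at 24, 48 and 96 hpf in control water, slick oil and source oil, with 3 replicate pools per group and 27 libraries in 9 groups. The deposited tables hold whole-number counts per miRNA name, without a species prefix and without scaling, in 6 tables of 3 control and 3 oil libraries each. The control libraries of a stage appear in both of its tables. Per the file headers, 6 further deposited tables hold the authors' DESeq2 log2 fold changes and the authors' p-values and adjusted p-values, whose unit is a p_value. The DESeq2 version, the aligner, the miRNA reference and the counting rule are not given in the sources used here. No genome coordinates were used.

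The counts were checked before use. Library totals lay between 51925 and 93055, and the name with the highest count took 0.758 to 1.204% of a library. The 27 pairs of replicates gave a chi-square per degree of freedom between 0.485 and 1.66, below 1 in 19 pairs, and held identical counts for 1.37 to 8.85% of names. This low, even distribution would also arise from counts of distinct sequences rather than reads, which nothing in the sources states, so the values are called counts. Merging names of identical counts reduced the 600 to 671 tested names to 488 to 569, and merging names of 1 miRNA number that differed by at most 5% reduced them to 342 to 388. Control counts differed between the tables of a stage for 38, 28 and 38 names at 24, 48 and 96 hpf, by at most 19, 5 and 21. Fits that joined tables used names with equal control counts, 913 of them over all tables. The slick table of 24 hpf holds 6813 blank lines, which were left out.

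Counts were analysed in R 4.3.3 with edgeR 4.0.16. Names were filtered with filterByExpr (min.count of 10), libraries were scaled by TMM, and groups were compared by edgeR's quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each oil group was compared with the controls of its stage in its own table. Slick and source oil were compared in 1 fit of the 9 libraries of a stage. Control stages were compared in 1 fit of 9 control libraries. The effect of each oil by stage was tested by both treatment-by-stage terms together over 18 libraries. Normalised counts are per 70000, and the errors given are SD over 3 libraries or the SE of the fitted log2 fold change. Slopes and covariances of the closing section are the exception, with an SE over miRNA numbers or, for the within-group slope, over groups. Fold changes of slick and source oil were correlated across names, beside 1000 simulations of unchanged groups against shared controls, with names drawn independently. Precision is limited by 3 libraries per group.

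Lists of miRNAs were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with the correlation estimated per list as an alternative and with fry. The 16 lists covered skeletal and cardiac muscle, heart, neural, retina and sensory organs, liver and gut, pancreas, red blood cells, leukocytes, vessels and smooth muscle, skin and epithelium, skeleton and connective tissue, the miR-430 family, the let-7 family, the miR-17-92 family clusters, p53 and stress, and the aryl hydrocarbon receptor. Lists, comparisons, the alternatives other than those named below as added, and the rule for named miRNAs were chosen before the data were examined. By that rule, among names past the threshold with a mean CPM of at least 10 and no overlap between groups, the 10 with the highest and the 10 with the lowest log2 fold change were named, with at most 3 called members per list and 13 miRNAs given in every oil comparison. The text gives some of these. Outside the rule, and chosen after their values were seen, are miR-204 under slick oil at 24 hpf, miR-144 under source oil at 96 hpf, the miRNAs given for the effect by stage, and the RNA fragments of the closing section.

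Alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, library size alone, no filter on low counts, a mean CPM of at least 50, the 5 highest names left out of the library size, identical names merged, replicate number as a block, all libraries of all stages in 1 fit, the oil groups alone, the authors' tables and leaving out each library in turn. The CPM limit turned out looser than filterByExpr. Added after the data were seen were cyclic loess over abundance, which removes a trend of fold change with abundance, merging within 5%, a mean count of at least 50, and closely agreeing replicates averaged (slick 1 and 2, source 1 and 3 at 24 hpf). Replicate numbers were treated as pairs only where deviations of same-numbered libraries correlated above 0.1 in all 3 pairs. The test was tested on simulated data: false calls were 2.22 to 5.43% of calls, and a log2 change of 1 was recovered in 90.9 to 97.0% of changed names and one of 0.5 in 40.3 to 75.0%. Simulated names were drawn independently, with at least Poisson spread and no trend over abundance. The data differ in these points, so the share of false calls in them was not measured. The test also shares its estimate of spread across names, so very small p-values and SE do not measure spread between 3 pools alone. Figures were drawn with matplotlib 3.10.9.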

Results

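MicroRNAs (miRNAs) were profiled in mahi-mahi, Coryphaena hippurus, at 24, 48 and 96 hours post fertilisation (hpf) by small RNA sequencing of whole embryos or larvae. At each stage animals were held in control water, in water prepared with oil collected from the sea surface after the Deepwater Horizon spill (slick oil), or in water prepared with oil from the well (source oil). Each of the 9 groups had 3 libraries, each from a pool of animals, which gives 27 libraries. The deposited counts summed to between 51925 and 93055 per library. The mean total at 24 hpf was 67232 ± 7059 (SD, n = 3) in controls, 65384 ± 2875 under slick oil and 54189 ± 2350 under source oil. At 48 hpf the means were 74857 ± 9151, 67263 ± 750 and 72988 ± 1758 in the same order. At 96 hpf they were 69630 ± 6080, 91344 ± 1791 and 88464 ± 1597, so both oil groups had higher totals than controls at that stage. No name took more than 1.204% of a library, the highest count of any name was 771, and 893 to 1005 names were detected per library. One mature sequence is often listed under several names with nearly the same counts, so the 600 to 671 names tested per oil comparison came from 119 to 124 miRNA numbers and are not independent. The first principal component of the 27 libraries held 55.2% of the variance, and 98.7% of its variance lay between stages. Group means below are normalised counts per 70000 counts, ± SD, with n = 3 per group. Log2 fold changes are given ± SE, and adjusted p-values are from edgeR's quasi-likelihood test.

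The untreated time course gave the background of stage against which the oil groups were set. From 24 to 48 hpf miR-144, a miRNA of developing red blood cells, rose in controls from 20.97 ± 1.97 to 229 ± 20.9 (log2 fold change 3.44 ± 0.13, adjusted p = 9.491e-15). miR-9-7-3p of the neural miR-9 group rose from 39.6 ± 3.08 to 209 ± 22.5, and miR-216a, which is enriched in the pancreas, rose from 30.8 ± 6.18 to 98.5 ± 15.8. The miR-430 family, which clears maternal mRNA in fish embryos, fell in all 8 of its tested names at both steps, and miR-430b went from 498 ± 22.8 to 248 ± 18.6 and then to 44.2 ± 9.39. From 48 to 96 hpf let-7a-5p rose from 96.2 ± 9.19 to 172 ± 14.3, the neuronal miR-124a rose from 54.8 ± 6.002 to 132 ± 7.37, and miR-144 fell to 104 ± 15.1. In the first step 274 of 605 names passed, 141 higher and 133 lower at 48 hpf. In the second step 355 of 605 passed, 179 higher and 176 lower at 96 hpf.

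Lists of miRNAs fixed in advance were tested between control stages, and camera called 15 of 32 tests with its preset correlation and 1 with an estimated correlation. When the control libraries were regrouped at random, 34 of 100 groupings, the real one included, gave at least 15 calls. Regrouped sets still mix libraries of stages that differ in many names, so their calls are not those of chance alone. The share therefore neither sets the number of called lists apart from chance nor shows that chance gives it. The call that held was the neural list in the first step, where 42 of 81 names rose and 6 fell (camera adjusted p = 1.026e-07; adjusted p = 0.0102 with an estimated correlation); adjusted over the list alone, 46 rose and 7 fell. The other 14 calls were lost with an estimated correlation, whose adjusted p is given in brackets. In the first step these were the miR-430 family with 0 of 8 names higher and 8 lower (0.0685), vessels and smooth muscle with 0 of 22 higher and 9 lower (0.0983), p53 and stress with 0 of 24 higher and 16 lower (0.160), skin and epithelium with 0 of 28 higher and 15 lower (0.263), skeleton and connective tissue with 14 of 19 higher and 2 lower (0.264), and liver and gut with 2 of 16 higher and 11 lower (0.365). In the second step they were the miR-430 family with 0 of 8 higher and 8 lower (0.0685), skeleton and connective tissue with 15 of 19 higher and 0 lower (0.0983), and the aryl hydrocarbon receptor list with 20 of 43 higher and 6 lower (0.0983). The liver and gut list had 16 of 16 higher (0.109), the miR-17-92 family clusters 0 of 47 higher and 29 lower (0.135), p53 and stress 14 of 24 higher and 4 lower (0.264), muscle 0 of 32 higher and 15 lower (0.330), and the let-7 family 17 of 24 higher and 4 lower (0.554).

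At 24 hpf the comparison of slick oil with controls asked which miRNAs differed early in exposure. miR-7641, an entry that has been questioned as a fragment of ribosomal RNA, rose from 21.96 ± 6.53 to 156 ± 16.7 (2.83 ± 0.17, adjusted p = 9.503e-07), and miR-365 rose from 12.3 ± 4.81 to 65.2 ± 9.72 (2.37 ± 0.24, adjusted p = 7.047e-05). miR-214 of the skeleton and connective tissue list rose from 4.17 ± 2.21 to 16.2 ± 3.95, and the neuronal miR-212 rose from 23.3 ± 9.09 to 72.9 ± 10.4. miR-204 of the eye rose from 136 ± 5.53 to 251 ± 27.1. The retina and sensory organ list, which holds it, had 16 of 33 names higher and 3 lower (camera adjusted p = 0.00837; adjusted p = 0.972 with an estimated correlation). Lower were the neuronal miR-124, at 24.97 ± 8.27 against 49.3 ± 4.08 (-0.96 ± 0.21, adjusted p = 0.00485), and miR-137, at 9.26 ± 1.24 against 19.2 ± 5.27. miR-216a was at 11.5 ± 2.16 against 27.3 ± 5.42, and miR-142-3p, a white blood cell miRNA, at 16.1 ± 6.07 against 31.9 ± 4.95, both lower. In the authors' fit miR-142-3p did not pass (adjusted p = 0.0947), and miR-214 and miR-137 were given no adjusted p. In all, 238 of 616 names from 72 of 123 miRNA numbers passed, 131 higher and 107 lower, and groups did not overlap in 52.6% of names, where chance gives 10% for 3 against 3. The count was 148 without control replicate 1, 149 with DESeq2 and 93 in the authors' table, and scaling by library size alone gave 107 higher and 140 lower.

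Under source oil at 24 hpf miR-7641 rose from 22.1 ± 6.59 to 115 ± 14.7 (2.39 ± 0.19, adjusted p = 2.211e-07), miR-365 from 12.3 ± 4.82 to 47.9 ± 1.55 and miR-212 from 23.1 ± 9.51 to 54.1 ± 4.99. miR-142-3p fell from 31.99 ± 4.97 to 13.5 ± 2.12 (-1.26 ± 0.25, adjusted p = 0.00176), miR-216a from 27.4 ± 5.45 to 11.6 ± 0.934 and let-7a from 93.2 ± 17.96 to 51.4 ± 2.94. miR-124 was lower, at 27.6 ± 3.67 against 49.5 ± 4.17. In the authors' fit miR-124 (adjusted p = 0.0700) and miR-216a (0.0545) did not pass, while miR-142-3p (0.0349) and let-7a (0.0115) did. The neural list had 24 of 74 names lower and 10 higher (camera adjusted p = 0.00170; adjusted p = 0.618 with an estimated correlation); adjusted over the list alone, 34 were lower and 10 higher. Its risers included miR-212 and miR-128-1-5p (1.29 ± 0.21). Of 600 names 158 passed, 85 higher and 73 lower, and groups did not overlap in 43.5%. The count was 82 without control replicate 1, 87 without source replicate 3, 57 with DESeq2 and 61 in the authors' table, and scaling by library size alone gave 65 higher and 91 lower. With the trend over abundance removed 77 were higher and 88 lower.

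**Figure D1:**
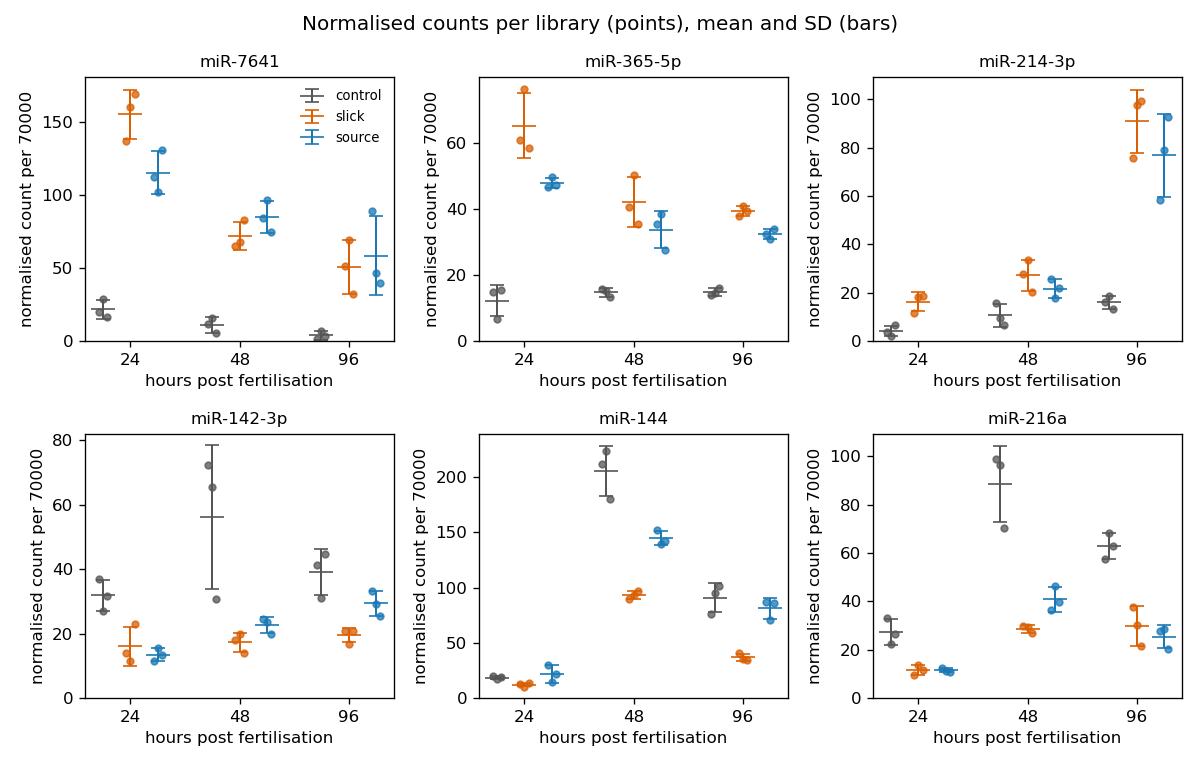
Normalised counts (per 70000) of 6 miRNAs in each library by stage and group, with points for libraries, horizontal bars for the group mean and error bars for 1 SD (n = 3). miR-7641 and miR-365-5p lay above every control library of their stage in both oils, and miR-216a lay below. miR-214-3p did not pass the low-count filter under source oil at 24 hpf and is not drawn there.

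At 48 hpf slick oil was accompanied by lower miR-144 and miR-142-3p. miR-144 fell from 205 ± 22.4 to 93.1 ± 3.60 (-1.15 ± 0.08, adjusted p = 1.011e-27) and miR-142-3p from 56.2 ± 22.3 to 17.3 ± 3.04 (-1.73 ± 0.22, adjusted p = 1.455e-12), while miR-451, the other main red blood cell miRNA, was at 10.2 ± 2.91 against 12.95 ± 3.59 and did not pass (adjusted p = 0.406). miR-216a fell from 88.6 ± 15.8 to 28.7 ± 1.58 and miR-219, a miRNA of myelin-forming cells, from 79.2 ± 12.2 to 30.8 ± 3.79. miR-7641 rose from 10.97 ± 5.23 to 71.9 ± 9.48, miR-365 from 14.7 ± 1.37 to 42.04 ± 7.51, and the p53-induced miR-34a-5p from 9.27 ± 3.51 to 20.5 ± 4.53. The retina and sensory organ list had 18 of 36 names higher and 2 lower (camera adjusted p = 1.183e-04; adjusted p = 0.972 with an estimated correlation), with miR-204 at 213 ± 13.1 against 139 ± 2.90. miR-124 was at 49.8 ± 6.27 against 50.8 ± 5.42 (adjusted p = 0.925). Of 642 names 262 passed, 125 higher and 137 lower, and groups did not overlap in 55.5%. DESeq2 called 132, and the authors' table holds 137.

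Under source oil at 48 hpf miR-144 fell from 206 ± 18.6 to 145 ± 6.56 (-0.52 ± 0.07, adjusted p = 4.528e-06), miR-142-3p from 56.2 ± 21.4 to 22.7 ± 2.45, miR-216a from 88.9 ± 13.99 to 40.8 ± 5.04 and miR-219 from 79.3 ± 8.85 to 40.7 ± 5.74. miR-7641 rose from 10.97 ± 5.11 to 85.2 ± 10.8 (2.89 ± 0.20, adjusted p = 6.228e-12), and the muscle miR-133b from 51.4 ± 6.55 to 86.6 ± 9.63. let-7b was at 47.9 ± 27.1 against 18.4 ± 3.79, with a wide spread among the oil libraries. Of 651 names 126 passed, 60 higher and 66 lower, and groups did not overlap in 38.6%. The count was 65 without control replicate 4, 66 without control replicate 5, 79 without source replicate 5, 43 with DESeq2 and 40 in the authors' table.

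At 96 hpf more names differed from controls than at the earlier stages. Under slick oil miR-214 rose from 16.01 ± 2.63 to 91.2 ± 13.5 (2.51 ± 0.18, adjusted p = 1.544e-14), miR-15c-5p from 14.4 ± 1.77 to 67.2 ± 7.87, the neuronal miR-132b from 9.22 ± 2.77 to 48.7 ± 6.56, miR-34a-5p from 8.84 ± 3.08 to 29.7 ± 6.45 and miR-7641 from 4.06 ± 3.05 to 50.9 ± 18.5. The red blood cell miRNAs moved apart: miR-144 was at 36.95 ± 3.36 against 90.6 ± 13.1 (-1.30 ± 0.14, adjusted p = 2.399e-10) and miR-451 at 43.4 ± 8.30 against 19.4 ± 2.92 (1.16 ± 0.21, adjusted p = 9.046e-06). The liver miR-122-5p fell from 309 ± 16.5 to 186 ± 26.5 and let-7a from 151 ± 12.8 to 81.7 ± 10.97. miR-122a-3p, of the other arm, was higher in the authors' fits at 96 hpf under slick oil (1.37, adjusted p = 5.673e-05) and source oil (1.15, adjusted p = 1.347e-04). The authors' log2 fold changes at 96 hpf run smaller than those given here, with slopes across names of 0.793 and 0.735. The miR-17-92 family clusters, tied to cell proliferation, had 26 of 48 names higher and 3 lower (camera adjusted p = 0.0146; adjusted p = 0.972 with an estimated correlation). Of 671 names 403 passed, 218 higher and 185 lower, and groups did not overlap in 66.0%. This balance depended on the scaling. DESeq2 size factors gave 213 higher and 191 lower, library size alone 238 and 151, and removal of the trend over abundance 180 and 181. Changes followed abundance: of 123 names with a mean count of 200 or more, 74 were lower and 14 higher, and of 268 names under 50, 28 were lower and 111 higher. Deviations of same-numbered libraries correlated at 0.141 to 0.176 here, above the limit of 0.1, though nothing in the labels says that equal numbers are pairs. With replicate number as a block 409 names passed.

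Under source oil at 96 hpf miR-214 rose from 15.9 ± 2.53 to 77.1 ± 17.7 (2.29 ± 0.19, adjusted p = 1.872e-17), miR-15c-5p from 14.3 ± 1.61 to 54.3 ± 4.87, miR-23-3p from 39.9 ± 10.97 to 102 ± 9.75 and miR-7641 from 3.996 ± 2.96 to 58.5 ± 26.9. miR-216a fell from 62.2 ± 4.29 to 25.4 ± 4.61. miR-144 was at 81.1 ± 9.18 against 89.7 ± 11.8 (adjusted p = 0.274) and did not pass, while the scarcer name miR-144-3p was lower, at 9.81 ± 2.79 against 21.9 ± 6.39 (-1.14 ± 0.23, adjusted p = 3.772e-04). miR-451 was at 31.1 ± 6.16 against 19.2 ± 2.71 (adjusted p = 0.00642), which did not pass in the authors' fit (adjusted p = 0.071). The miR-17-92 family clusters had 25 of 46 names higher and 2 lower (camera adjusted p = 0.00170; adjusted p = 0.972 with an estimated correlation). The let-7 family had 11 of 28 names lower and 0 higher (camera adjusted p = 0.0320; adjusted p = 0.972 with an estimated correlation). Of 661 names 317 passed, 187 higher and 130 lower, and groups did not overlap in 61.3%. The balance of directions moved with the scaling. DESeq2 size factors gave 169 higher and 150 lower, library size alone 204 and 111, and removal of the trend over abundance 145 and 136. Of 112 names with a mean count of 200 or more, 68 were lower and 4 higher, and of 272 names under 50, 17 were lower and 94 higher.

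**Figure D2:**
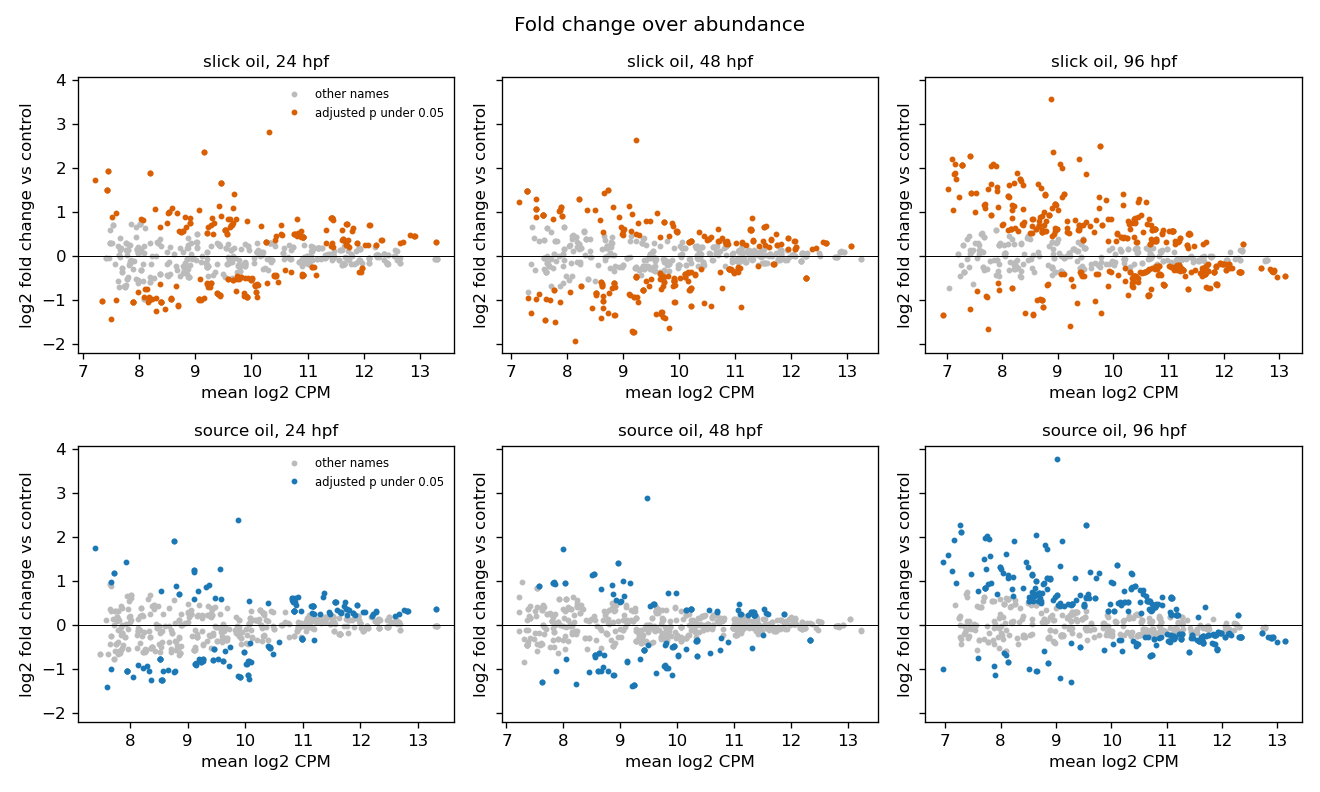
Log2 fold change against control (vertical axis) over mean log2 CPM (horizontal axis) for each oil and stage, coloured where the adjusted p was under 0.05. At 96 hpf scarce names lie mostly above 0 and abundant names mostly below it, with Spearman's rho across names, which are not independent replicates, of -0.319 under slick oil and -0.343 under source oil.

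The muscle miRNAs fixed in advance did not move together. miR-499-5p was lower in 5 of the 6 oil comparisons, at -0.67 ± 0.08 under slick oil at 96 hpf, and was -0.23 ± 0.07 under source oil at 48 hpf, which did not pass. In the authors' fits it did not pass at 24 hpf either, under slick oil (adjusted p = 0.0632) or source oil (0.258). miR-133a was higher at 96 hpf, at 0.57 ± 0.08 under slick oil and 0.63 ± 0.08 under source oil. miR-206 was higher at 24 hpf, at 0.33 ± 0.08 and 0.37 ± 0.08, and under slick oil at 48 hpf, at 0.23 ± 0.05 (adjusted p = 2.389e-05), while source oil at 48 hpf did not pass, at 0.14 ± 0.08 (adjusted p = 0.260). It was lower at 96 hpf, at -0.28 ± 0.06 and -0.17 ± 0.05, but at 96 hpf its sign turned to 0.01 and 0.09 when the trend of fold change over abundance was removed. miR-1 was lower at 96 hpf, at -0.18 ± 0.06 (adjusted p = 0.0109) and -0.18 ± 0.06 (adjusted p = 0.0192), and with that trend removed it was 0.01 and -0.01 and did not pass. The hypoxia-induced miR-210 was lower under slick oil at 48 hpf, at -0.52 ± 0.17, and higher under source oil at 96 hpf, at 0.61 ± 0.14. In the authors' fits the first did not pass (adjusted p = 0.108) and the second did (0.0171). miR-34b-5p was higher at 48 hpf, at 1.06 ± 0.25 (adjusted p = 0.00341) and 0.95 ± 0.28 (adjusted p = 0.0211). It was also higher at 96 hpf, at 1.75 ± 0.27 and 1.33 ± 0.24. At 24 hpf it was 0.94 ± 0.36 under source oil (adjusted p = 0.0664) and was not tested under slick oil. The 48 hpf changes did not pass in the authors' fits (0.0502 and 0.270). Its effect by stage did not pass in either oil (0.239 and 0.972). miR-430b was higher at 96 hpf, at 0.68 ± 0.16 and 0.70 ± 0.15. miR-21 was lower at 96 hpf, at -0.27 ± 0.06 and -0.22 ± 0.06, beside medians of -0.23 and -0.22 over names with a mean count of 200 or more. Its effect by stage passed (adjusted p = 5.490e-04 under slick and 3.129e-04 under source oil). With the trend over abundance removed that effect did not pass (0.706 and 0.910). miR-203 passed in none of the 6 comparisons, and with the trend over abundance removed it passed as lower at 24 hpf (-0.16 and -0.13) and as higher at 96 hpf (0.23 and 0.22).

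**Figure D3:**
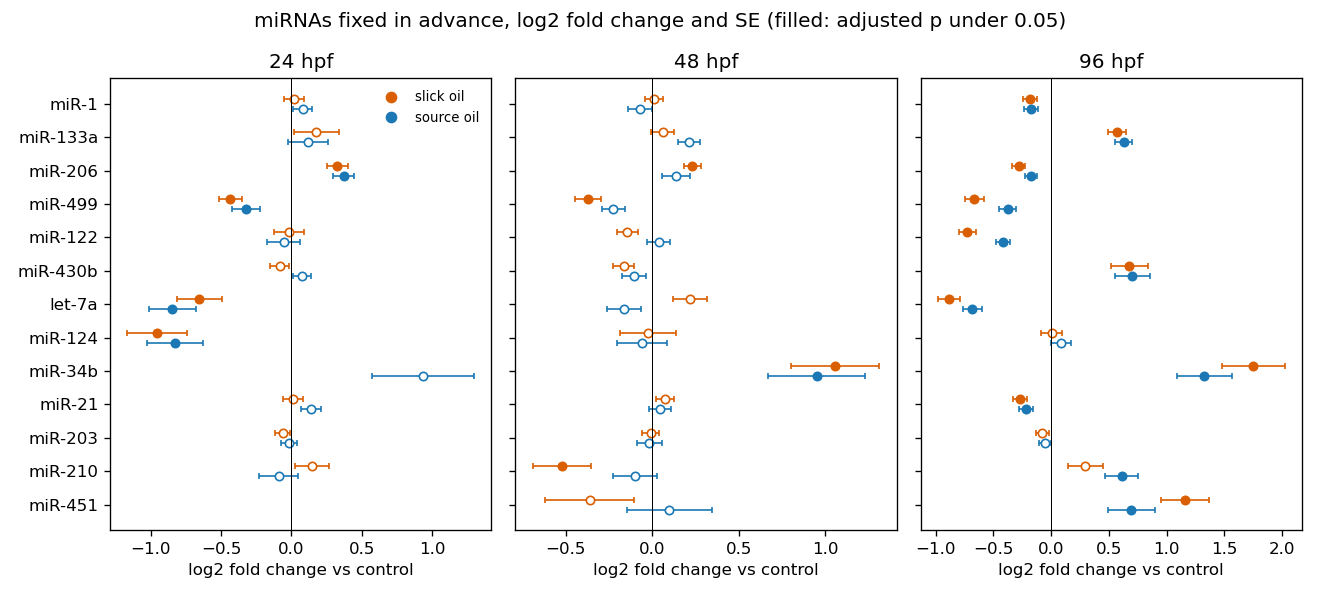
Log2 fold change against control (horizontal axis) of the 13 miRNAs fixed in advance at 24, 48 and 96 hpf under slick and source oil, with bars for 1 SE and filled points where the adjusted p was under 0.05. let-7a lies at -0.89 under slick oil and -0.68 under source oil at 96 hpf, and a missing point marks a miRNA that was not tested. Each point is the name of that miRNA with the highest mean count. Hence let-7a-5p (0.22 ± 0.10) is drawn for let-7a under slick oil at 48 hpf, and miR-210-5p for miR-210 at 24 hpf. The name let-7a itself was lower under slick oil at 48 hpf, at -0.42 ± 0.11 (adjusted p = 0.00492). It did not pass there in the authors' fit (adjusted p = 0.0802).

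Fold changes under slick and source oil were set against each other at each stage, both resting on the same 3 control libraries. Across names, which are not independent replicates, Pearson's r was 0.876 at 24 hpf, 0.892 at 48 hpf and 0.937 at 96 hpf, where unchanged groups simulated against shared controls gave 0.498, 0.501 and 0.499. The covariances were 0.222, 0.194 and 0.350, against simulated values of 0.0170, 0.0114 and 0.0107. The simulation drew each name independently, which the names here are not, so its values do not show how far chance can carry r. Random regroupings of the 9 libraries of each stage mix oil and control libraries. Their highest correlations were 0.857, 0.887 and 0.967 at 24, 48 and 96 hpf. At 24 hpf 73 names were higher and 67 lower in both oils, at 48 hpf 48 and 63, and at 96 hpf 173 and 120, and 0 names passed in opposite directions. Shared controls alone raise such overlaps, and no expected number was simulated for them or for the names called in all 6 comparisons. The 3 controls cannot be divided into 2 sets of at least 2 libraries, so their share in these values was not measured apart from the simulation. In all 6 comparisons 13 names of 7 miRNA numbers were higher (miR-7641, miR-365, miR-212, miR-128-1-5p, miR-20b, miR-23-3p and miR-92) and 12 names of 5 numbers were lower (miR-101, miR-216a, miR-21b-3p, miR-725-3p and miR-9). In the authors' fits miR-216a did not pass under source oil at 24 hpf (adjusted p = 0.0545).

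**Figure D4:**
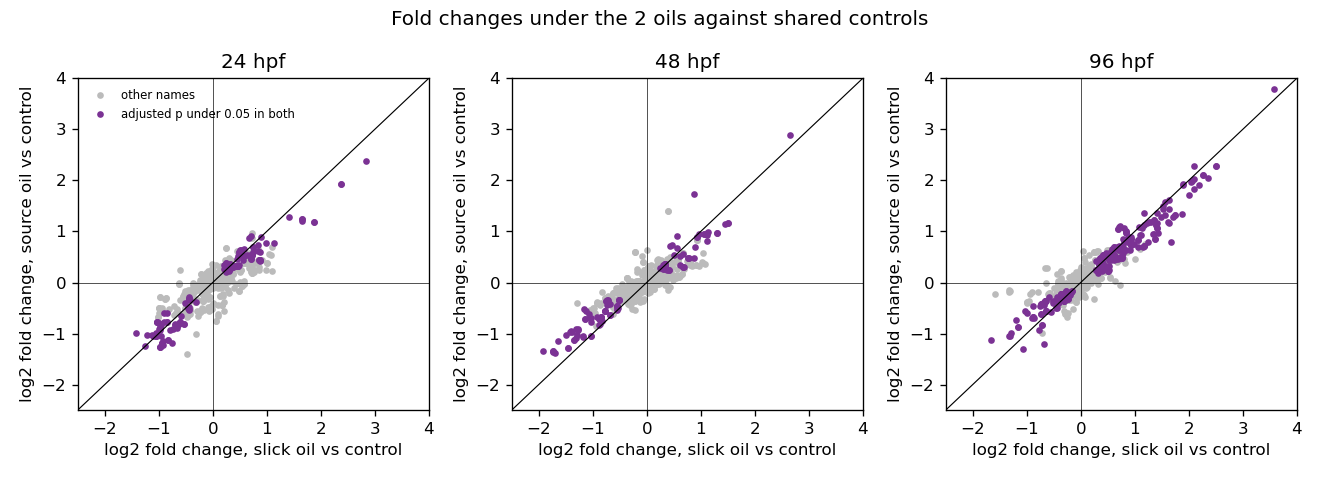
Log2 fold change against control under source oil (vertical axis) over that under slick oil (horizontal axis) at each stage, one point per name, with names called in both oils in purple and the line of equality. Of the names called in both oils, 85 of 140 at 24 hpf, 95 of 111 at 48 hpf and 223 of 293 at 96 hpf had the larger change under slick oil.

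The direct comparison of the oils asked where they differed at the same nominal loading. miR-204 was higher under slick than source oil at 48 hpf, at 221 ± 13.3 against 156 ± 6.54 (0.50 ± 0.06, adjusted p = 4.018e-06). At 96 hpf it was at 226 ± 17.8 against 183 ± 5.18 (adjusted p = 0.00413), which was lost with DESeq2 (0.336) and without slick replicate 9 (0.0701). At 24 hpf it was at 261 ± 27.2 against 194 ± 17.8 (adjusted p = 0.0350), which was lost with DESeq2 size factors (0.0546), the highest names left out (0.0900), identical names merged (0.0501), names merged within 5% (0.0889), the oil groups alone (0.201) or DESeq2, and in 7 of 9 fits with a library left out. miR-144 was lower under slick oil at 48 hpf, at 96.7 ± 4.02 against 148 ± 6.66, and at 96 hpf, at 39.4 ± 3.35 against 85.6 ± 9.75 (-1.11 ± 0.13, adjusted p = 1.714e-09). miR-206-5p was higher under slick oil at 24 hpf, at 79.3 ± 10.3 against 43.2 ± 1.35 (adjusted p = 0.0213), which was lost with DESeq2, the oil groups alone (0.110) and in 4 of 9 fits with a library left out. miR-122-5p was lower at 96 hpf, at 198 ± 27.6 against 242 ± 16.5 (adjusted p = 0.0128), which was lost with DESeq2 (0.336), without slick replicate 9 (0.376) and without source replicate 7 (0.154). At 24 hpf 7 of 603 names passed, all higher under slick oil (miR-206-5p, miR-462, miR-211 and 4 names of miR-204). This count was 1 without control replicate 1, 2 or 3, 0 without slick replicate 1 or 2 or source replicate 1 or 3, and 11 without slick replicate 3. Another split of the 6 oil libraries of 24 hpf called 90 names. With DESeq2, 0 passed at 24 hpf, where edgeR's unadjusted p was under 0.05 for 76 names. At 48 hpf 35 of 637 passed, 31 higher and 4 lower, and the count was 23 without slick replicate 4 or 6, 20 without source replicate 6 and 14 with DESeq2. At 96 hpf 29 of 669 passed, 13 higher and 16 lower, and the count was 56, 15 and 5 without slick replicates 7, 8 and 9, 15 and 16 without source replicates 7 and 9, and 4 with DESeq2. With the trend over abundance removed the calls were 23 higher and 8 lower at 48 hpf, and 15 higher and 10 lower at 96 hpf.

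The test of the oil effect by stage asked whether an oil's effect differed between 24, 48 and 96 hpf. Under slick oil it passed for miR-206 (adjusted p = 1.411e-05), miR-122-5p (1.411e-05), miR-212 (1.928e-05) and miR-15c-5p (3.628e-04), and under source oil for the same miRNAs (2.442e-04, 2.468e-04, 0.00606 and 9.712e-04). With the trend over abundance removed miR-206 did not pass in either oil (0.0934 and 0.514). miR-7641, miR-216a and miR-142-3p did not pass under slick oil (0.558, 0.366 and 0.252) or source oil (0.304, 0.543 and 0.113). In all, 286 of 691 names passed under slick oil and 227 of 704 under source oil. The slick count was 127 with DESeq2, 126 with the trend over abundance removed and 179 without control replicate 8 of 96 hpf. The source count was 82 with DESeq2 and 57 with the trend removed, and it lay between 89 and 185 when each of the 18 libraries was left out in turn, so each of these fits gave fewer names than all 18 together. It was 120, 122 and 122 without control replicates 1 and 3 and source replicate 2, 135, 143 and 151 without control replicate 4 and source replicates 5 and 6, and 106, 92, 124, 126 and 89 without control replicates 7, 8 and 9 and source replicates 8 and 9. The direction of these calls depended on the scaling. Direction was taken from the change of the effect from 24 to 96 hpf alone, also for names called for their change at 48 hpf. By it 100 were higher and 186 lower under slick oil and 53 and 174 under source oil. With DESeq2 size factors they were 122 and 134, and 66 and 87. With library size alone they were 148 and 69, and 108 and 51, and with the trend removed 71 and 55, and 33 and 24. Against the median over all names, library size alone moved these changes by 0.23 under slick oil and 0.29 under source oil, and DESeq2 size factors by 0.12 under source oil.

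Over the 6 oil comparisons camera called 6 of 96 list tests, 4 higher and 2 lower, and 0 held with an estimated correlation. fry, which asks whether a list's names move one way on balance, called 11 after adjustment, and in 86 tests a list held changes in either direction. The median, mean and test of a list differed in sign in 35 of the 96 oil tests and 4 of the 32 control tests, and 0 of these were called. On names shared by both tables of a stage the real number of calls was 7. When the 9 libraries of each stage were regrouped at random, 79 of 100 groupings, the real one included, gave at least 7. Regrouped sets still mix oil and control libraries, whose differences they carry. The share thus neither sets the list calls under oil apart from chance nor shows that chance gives them. At 96 hpf 12 of 15 red blood cell names were higher under each oil, with 3 lower under slick oil and 1 under source oil; with the trend over abundance removed 3 were higher and 2 lower under source oil. Camera did not call the list (adjusted p = 0.155 in both). The lists of muscle, heart, liver and gut, pancreas, leukocytes, vessels and smooth muscle, skin and epithelium, skeleton and connective tissue, the miR-430 family, p53 and stress, and the aryl hydrocarbon receptor were called in 0 oil comparisons.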

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

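All results in this part come from tests of a difference between effects; the repeat of those tests after removing the trend of fold change over abundance was chosen after the results were seen.

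The effect of slick oil differed between stages for 286 names and that of source oil for 227. Oil and control labels were regrouped at random within each stage. Of 100 groupings of the 18 libraries, the real one included, 3 gave as many under slick oil (highest other 381). Under source oil 3 did (highest other 294). At the 0.05 level this excludes chance only for an oil effect of some kind. Regrouping also breaks up an effect that is equal at all stages, so it cannot show that the effect differs between stages. Among the named miRNAs the slick effect differed for let-7a (adjusted p = 0.0121), miR-1 (0.0159), miR-122-5p (1.411e-05), miR-124 (0.00331), miR-15c-5p (3.628e-04), miR-204 (0.0128), miR-206 (1.411e-05), miR-21 (5.490e-04), miR-210 (0.0464), miR-212 (1.928e-05), miR-365 (0.0211), miR-430b (0.00658), miR-451 (0.00320), miR-499-5p (0.0113) and miR-92b (0.00803). The source effect differed for let-7a (0.00243), miR-1 (0.00593), miR-122-5p (2.468e-04), miR-124 (0.0268), miR-15c-5p (9.712e-04), miR-204 (0.0283), miR-206 (2.442e-04), miR-21 (3.129e-04), miR-212 (0.00606), miR-430b (0.0157) and miR-92b (0.0171). With the trend over abundance removed, miR-122-5p, miR-15c-5p, miR-212 and miR-430b still passed in both oils, let-7a passed under source oil, and miR-124, miR-365 and miR-451 passed under slick oil, while the others named here did not. 3 further named miRNAs passed only with the trend removed: miR-203 (5.455e-04 under slick and 2.704e-04 under source oil), miR-133a (0.0180 and 0.0337) and, under slick oil alone, miR-144 (0.0411).

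The direct difference between slick and source oil passed for 7 names at 24 hpf, 35 at 48 hpf and 29 at 96 hpf. With 10 splits of the 6 oil libraries a share under 0.05 cannot be reached. At 24 hpf 2 of the 10 splits gave at least 7 names, and the other called 90, for slick replicates 1 and 2 with source replicate 2 against slick replicate 3 with source replicates 1 and 3, which points to a structure of these libraries other than the oil. At 48 and 96 hpf the highest other split called 0.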

How the results depend on the processing

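Loess over abundance, merging within 5%, a mean count of at least 50 and the averaging of replicates were chosen after the results were seen; the other alternatives were planned. In the order slick then source at 24, 48 and 96 hpf, oil calls fell to 131, 86, 152, 73, 227 and 177 with names merged within 5%, and to 125, 80, 150, 63, 249 and 196 with a mean count of at least 50, both of which test fewer names. At 24 and 48 hpf DESeq2 called 149, 57, 132 and 43 and the authors' fits held 93, 61, 137 and 40; the cause was not tested. Control steps gave 168 and 210 after merging and 176 and 224 with the higher count limit. Slick against source at 24 hpf gave 1 with DESeq2 size factors, the highest names left out, identical names merged or merging within 5%, and 0 with DESeq2 or the oil groups alone. At 48 hpf it gave 22 with library size alone, 14 with DESeq2 and 15 after merging within 5%, and at 96 hpf 4 and 15 with the latter. The slick effect by stage gave 127 with DESeq2, 126 with loess, 110 after merging and 131 with the count limit. The source effect by stage gave 82, 57, 78 and 138 in the same order, 148 with the highest names left out and 149 with identical names merged. List calls under oil fell from 6 to 0 with an estimated correlation and after merging within 5%, and control list calls from 15 to 1 with an estimated correlation. The cause of these moves was not tested beyond the smaller number of names.

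Leaving out each library in turn gave 148 to 240, 82 to 175, 189 to 254, 65 to 124, 350 to 385 and 260 to 317 oil calls in the order above, 0 to 11, 20 to 39 and 5 to 56 between oils, 238 to 284 and 320 to 364 between control stages, 179 to 283 and 89 to 185 for the effects by stage, 4 to 8 and 14 to 16 list calls, and correlations of 0.817 to 0.899, 0.864 to 0.907 and 0.924 to 0.940. Loess turned the sign of miR-1 (0.00708) and miR-206 (0.0144) under slick oil, of miR-183-5p (0.0211) and miR-206 (0.0907) under source oil, and of miR-203 under both (0.232 and 0.216), all at 96 hpf. Of the values of named miRNAs, 85 with DESeq2, 24 with loess and 275 with a library left out kept their sign and no longer passed, beside those that loess turned. So did 14 with library size alone, 11 without a filter, 10 with the oil groups alone and 0 to 8 under each other alternative. Under alternatives other than loess 0 that passed before or after turned sign.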

Other observations

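Of the tests in this part, those of levelling counts, RNA fragments and slower development were chosen after the results were seen, and the regroupings of libraries were planned. Standard errors of covariances and observed slopes come from resampling miRNA numbers with the libraries held fixed. The SE of the within-group slope comes from leaving out each group in turn. They measure spread over names or groups and not between the 3 libraries of a group. Limits set in these standard errors are therefore not tests between libraries.

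At 96 hpf the oil fold changes followed abundance, with totals 31.5% higher under slick oil and 27.3% higher under source oil than in controls. Counts that level off as totals rise may account for this order. Within groups the slope of log2 count on abundance changed by -0.241 (SE 0.0503) per doubling of the total over 583 names, which predicts slopes of -0.0952 and -0.0840 where -0.146 and -0.124 were observed, at most 1.45 standard errors apart. It is not the whole cause of the calls, since with the trend removed 294 of 403 slick calls and 202 of 317 source calls, or 63.7% at the lowest, passed in the same direction. An effect of the oils on many miRNAs at once stays open for the rest of the order. Under source oil at 24 hpf, with totals 19.2% below controls, the order was opposite. Its slope was 0.0622 (SE 0.0198) where 0.0740 was predicted. For slick oil at 24 and 48 hpf and source oil at 48 hpf the slopes were 0.0327, 0.00407 and -0.00448. The predicted ones were 0.00867, 0.0354 and 0.00706.

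miR-7641 was higher in all 6 oil comparisons. Levelling counts are argued against, because with the trend over abundance removed its lowest log2 fold change was 2.55. More fragments of ribosomal and transfer RNA under oil could raise it, but only 1 other such name, miR-2478, had a mean count of at least 5. Its log2 fold change lay between -1.004 under source oil at 24 hpf (adjusted p = 0.00224), the only comparison in which it passed, and 0.05 under slick oil at 96 hpf. miR-6240, at mean counts of at most 3.50, was higher at 24 hpf (3.98 and 3.61) and 96 hpf (5.63 and 5.27) and not at 48 hpf (-0.39 and -0.49), and miR-1260, at mean counts of at most 4.33, passed only under slick oil at 96 hpf (4.59, adjusted p = 0.00377). With so few names, fragments and a response to oil cannot be told apart.

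Fold changes under oil at 96 hpf ran against the control change from 48 to 96 hpf, with a covariance, less that of the shared controls, of -0.0848 (SE 0.0316) under slick oil and -0.0609 (SE 0.0288) under source oil. Set against the change from 24 to 48 hpf, those at 48 hpf gave -0.0686 (SE 0.0378) and -0.0594 (SE 0.0258), and those at 24 hpf 0.00361 (SE 0.0339) and -0.0292 (SE 0.0274). Slower development under oil may give values below 0, but with the trend over abundance removed only 1 of the 6 comparisons, source oil at 48 hpf, lay below 0 by more than 2 standard errors. The others at 24 and 48 hpf were then 0.0201 (SE 0.0339) and -0.0570 (SE 0.0380) under slick oil and -0.00582 (SE 0.0263) under source oil at 24 hpf. For source oil at 48 hpf levelling counts are argued against, because removing the trend left -0.0538 (SE 0.0253) and totals were 2.01% below those of controls. This comparison was picked out after all 6 values were seen. At 96 hpf levelling counts may add to the values: removing the trend left -0.0475 (SE 0.0298) and -0.0311 (SE 0.0272). The limit for the test at 96 hpf was tightened from 2 to 1 standard errors of 0 after its value, which met the first and not the second, was seen. At 96 hpf slower development and levelling counts cannot be told apart, because the values left are below 0 by less than 2 standard errors, and slower development under source oil at 48 hpf stays open.

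For each oil against its controls and each step between control stages, 3 against 3 libraries make 10 splits, too few for a share under 0.05. The real splits gave 238, 158, 262, 126, 403 and 317 names for slick and source oil at 24, 48 and 96 hpf and 274 and 355 for the control steps, and the highest other split gave 0 in each. Only slick oil at 96 hpf met the limit for treating replicate numbers as pairs, which does not establish pairing. Its 3 other splits that part as many same-numbered libraries also gave 0. For the correlation of slick with source fold changes, 1, 1 and 2 of 100 regroupings, the real one included, gave one as high as the real. The real values on shared names were 0.874, 0.892 and 0.936, and the highest others were 0.857, 0.887 and 0.967. At the 0.05 level this excludes chance only for a difference of some kind among the libraries of a stage. Controls that differ from both oil groups for any reason would raise this correlation, so it cannot show that the oils act alike. For the lists chance is not excluded. Under oil 79 of 100 regroupings gave at least the real 7 calls (highest other 22). Between control stages 34 of 100 gave at least the real 15 (highest other 20). These regroupings still mix libraries of groups that differ, so they do not show that chance gives the calls either.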
